A study of Homo sapiens with 4 samples.

How the data were processed

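Expression was measured on 4 Affymetrix arrays of biotin-labelled total RNA from primary human tracheal epithelial cultures, 1 array for each of 4 groups: no RA, RA at 30 nM, IL-6 at 10 ng/ml for 24 hours and IL-17A at 10 ng/ml for 24 hours. RNA was extracted with Trizol, per the labels' protocols. The labels do not say which donor or donors the cultures came from, whether the cytokine cultures also received RA, or how long RA was given.

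The deposited tables hold a signal intensity on a linear scale for each of 22283 probe sets on each array, and one of them also holds the deposited detection call and detection p-value of each probe set. The software that made these values and its settings are not given in the sources used here. The deposited intensities had 2% trimmed means between 125.05 and 125.06, so the arrays carry a common scaling, which fixes their overall level and hides any change in total RNA per cell. Both deposited tables held identical intensities for all 22283 probe sets. By the deposited detection p-values, a probe set was called present below 0.04 and absent from 0.06. No genome build is named in the files, so no coordinates are given.

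Gene names came from the platform annotation table, where 19071 probe sets had 1 gene symbol, 1043 had several and 2101 had none. Symbols were updated through gene identifiers in a RefSeq gene table of assembly GRCh38.p14, used for names only, which matched 19059 probe sets and left 12 with their old symbol. Probe sets with several symbols were not used, which leaves out DEFB4A. Genes of X inactivation, Y-linked genes and genes whose expression is set by a person's genotype were left out of all steps (144 probe sets), as were 68 control probe sets. This left 11874 genes, of which 4277 had more than 1 probe set. Each gene was represented by its probe set with the highest mean log2 signal over the arrays, and the other probe sets were used as a check.

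The precision is limited by the number of arrays. The floor for dim signals was 34.8, the highest over the arrays of the 75th percentile of signals called absent. Signals below it were raised to it before log2 was taken. No fold was given where both arrays were at the floor or both were called absent. Where only the dimmer array was at the floor or absent, the fold is a lower bound, computed from the higher of the floor and the dim signal. The 3' to 5' signal ratio of ACTB, a sign of RNA integrity, was 2.58 without RA, 2.25 with RA, 1.80 with IL-6 and 2.38 with IL-17A, and that of GAPDH was 2.20, 1.69, 1.58 and 1.61. Log2 signals of the 4596 genes present on all arrays correlated across genes with r between 0.909 (RA with no RA) and 0.979 (IL-17A with IL-6).

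With 1 array per group no test across samples was possible, and no p-value was computed. Genes were counted at a 2-fold threshold as a description of these arrays. RA was compared with no RA and IL-17A with IL-6. Each cytokine was compared with both arrays without cytokine, and a gene counted only if it passed 2-fold in the same direction over each, ranked by the smaller of the ratios. For gene lists, ratios were taken over the mean log2 signal of the arrays without cytokine, and over each alone. A list's median was set against 10000 random lists of the same size drawn from the same 10 expression bins. To show what arrays without any change would give, 100 sets of arrays were simulated with a spread taken from the IL-17A and IL-6 arrays in 20 brightness bins. That spread is normal in shape and includes any real difference between these arrays, and it understates rare large deviations. It gives no reference for IL-17A over IL-6, the arrays it was taken from. These were the most alike pair of arrays, so the spread may be too narrow for the other comparisons. The counting step was tested on simulated data for IL-17A over both arrays, with 200 of 11874 genes changed in each of 20 draws. The changed genes were drawn only from those with a mean signal well above the floor. Of these it called 1.9% of genes changed 1.5-fold, 95.8% of those changed 3-fold and 100.0% of those changed 6-fold, with at most 12 unchanged genes called in a draw. These shares do not hold for dim genes, which were not tried.

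The gene lists were 17 in number, with 597 memberships: squamous and cornified envelope, mucous and secretory airway, ciliated cell, basal cell, retinoid target and metabolism, IL-17A and NF-kB target, IL-6 and STAT3 target, interferon response, cell cycle, cholesterol synthesis, stress and heat shock, extracellular matrix and fibroblast marker, leukocyte marker, endothelial marker, cartilage marker, ribosomal protein, and cytokine receptor and signalling. The lists, the comparisons, the floor, the 2-fold threshold, the rule for named genes and all alternatives but 2 were chosen before the data were examined. The rule named, for each comparison, the 12 genes with the largest increase and the 12 with the largest decrease among those at least 2-fold different with the brighter array called present, up to 4 members of each list with the largest ratios, and MUC5AC, MUC5B, IL6, CXCL8, CCL20, SOCS3, CYP26A1, RARB, KRT13, TGM1 and SPRR1B. Other members of a list are named where they passed 2-fold, and the genes shared by both cytokines are named in full, both chosen after their values were seen. The second probe sets of MUC5AC and SOCS3 were also looked at after the brightest ones were found absent.

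The alternatives were quantile normalization, centring of each array on its median ratio, the floor at 0.25 times its value or doubled, the mean of a gene's probe sets, leaving out probe sets with shared sequence, the present call in place of the floor, thresholds of 1.5-fold and 3-fold, and each control array alone. The alternatives added after seeing the data were the present call with the floor kept and a requirement for another measured probe set in the same direction. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.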

Results

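Gene expression was measured on 4 Affymetrix arrays, 1 per group, from human tracheal epithelial cells in primary culture, which are airway lining cells taken from tissue and not an established line. The groups were a basal control culture without retinoic acid, a culture given 30 nM all-trans-retinoic acid (RA, the vitamin A derivative that airway epithelial cultures need for mucous differentiation), a culture given 10 ng/ml of the cytokine IL-6 for 24 hours and a culture given 10 ng/ml of the cytokine IL-17A for 24 hours. The deposited signals had been scaled to a common level, with a 2% trimmed mean of 125.06 on the arrays without RA, with RA and with IL-17A and 125.05 on the IL-6 array. Probe sets called present made up 36.8% of 22283 on the array without RA, 38.3% with RA, 40.1% with IL-6 and 38.9% with IL-17A. With 1 array per group there was no replicate spread to set a difference against, so no test was run and every difference below describes these arrays only. Signals below the floor of 34.8 were raised to it, and a fold is written as a lower bound ("at least") where the dimmer array was at that floor or called absent.

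The first comparison asked which genes differed between the cultures with and without RA. The genes lower with RA included members of the squamous, skin-like programme. TGM3, a transglutaminase that crosslinks the cornified envelope, was at least 53.5-fold lower (2740.6 without RA and 51.2 with it), KRT16, a keratin of stressed and stratified epithelium, was 23.2-fold lower (7510.2 and 324.0), and IVL, the envelope protein involucrin, was 12.8-fold lower (1317.0 and 102.7). Some secretory genes were higher: BPIFA1, a secreted airway surface protein, was 16.8-fold higher (382.4 and 6439.3), and MUC4, a membrane mucin, was 9.27-fold higher (88.0 and 816.0). CYP26A1, the enzyme that breaks down RA, was at least 22.3-fold higher (79.1 and 1760.8), and DHRS3, which reduces retinal to retinol, was at least 14.9-fold higher (73.2 and 1093.3).

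Among 6063 genes with a fold, 477 were at least 2-fold higher with RA and 416 at least 2-fold lower. SERPINA3, a secreted protease inhibitor of the acute phase response, was at least 61.5-fold higher (11.5 and 2139.7). Complement genes C3 and CFB were 14.2-fold and at least 13.1-fold higher. IGFBP3, which binds insulin-like growth factors, was 12.8-fold higher, PLAT, the tissue plasminogen activator, was 11.4-fold higher, and FCGBP, a mucin-like secreted protein, was at least 10.6-fold higher. HSPG2, which encodes perlecan of the basement membrane, and the matrix metalloproteinase gene MMP28 were at least 12-fold and at least 8.73-fold higher. In the other direction MAL, which encodes a membrane-raft protein of apical transport, was 54.3-fold lower (2434.7 and 44.8), and HOPX, a homeodomain protein without DNA binding, was 28.2-fold lower (7850.5 and 278.5). SLURP1, a secreted epidermal peptide, CALML5, a calmodulin-like protein of keratinocytes, and KLK12, a kallikrein protease, were at least 24-fold, at least 18.9-fold and at least 15-fold lower. CLIC3 was 20.3-fold lower, and LY6G6C and SCGB2A1 were at least 16.9-fold and at least 11.3-fold lower. EGFR, the epidermal growth factor receptor, was at least 15.7-fold lower on its brightest probe set, but its other measured probe sets gave log2 ratios of 0.53 and -0.47.

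**Figure D1:**
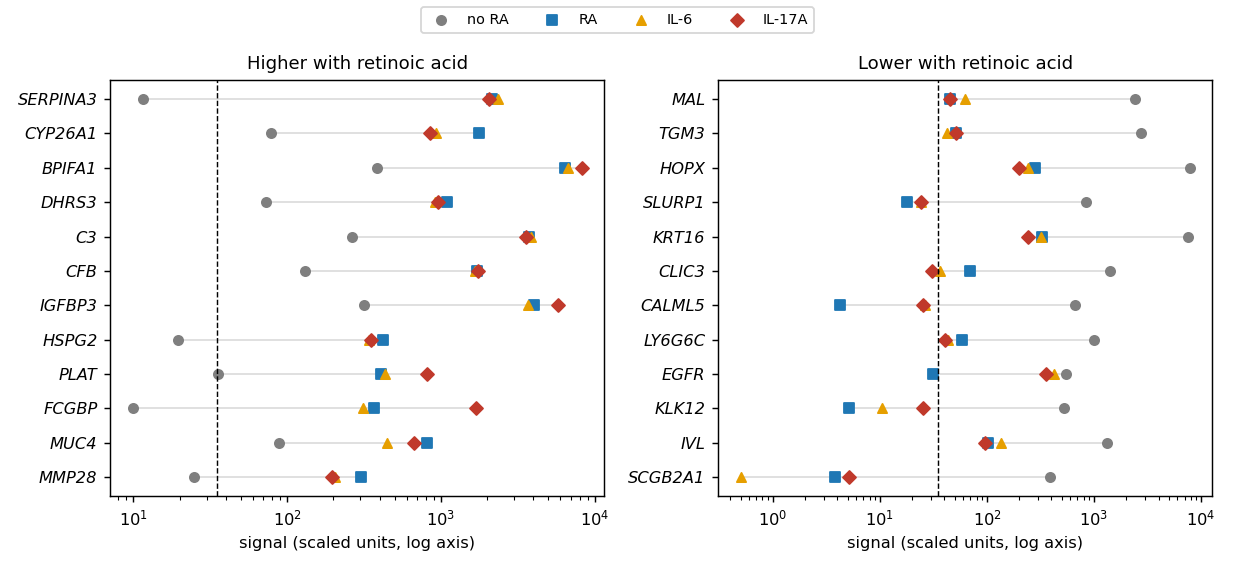
Signal on each of the 4 arrays (log axis, scaled units) for the 12 genes with the largest increase and the 12 with the largest decrease between the arrays with and without RA on floored values, 1 array per group and 1 probe set per gene, with the floor of 34.8 as a dashed line. SERPINA3 reads 11.5 without RA and 2139.7 with it, and on EGFR the RA array lies apart from the other arrays.

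Of 25 members of the squamous and cornified envelope list with a fold, 16 were at least 2-fold lower with RA and 1 was at least 2-fold higher. The list's median log2 ratio was -1.65, and 95 percent of random lists matched on expression lay between -0.36 and 0.30. The lower members included KLK7, a desquamation protease (at least 8.14-fold), and the small proline-rich envelope proteins SPRR1B (10239.0 and 5039.3) and SPRR2B (2941.9 and 370.4). The higher member was SERPINB4, a squamous cell protease inhibitor. TGM1, another envelope transglutaminase, was 1.87-fold lower, and KRT13, a keratin of non-cornified stratified epithelium, was 1.75-fold higher. In the mucous and secretory airway list 10 of 19 members were at least 2-fold higher and 1, the retinaldehyde dehydrogenase gene ALDH1A1, was at least 2-fold lower, with a median of 1.04 against a random range of -0.43 to 0.36. They included SPDEF, a transcription factor of goblet cells (at least 6.03-fold), the club cell gene SCGB1A1 (474.8 and 1551.9), the membrane mucin gene MUC1 (1430.8 and 3897.7) and AGR2 (682.6 and 1847.0), which acts in mucin folding. For the secreted gel-forming mucin MUC5AC the brightest probe set was called absent on every array, and a second one was absent without RA (5.1) and present with RA (119.0), at least 3.42-fold higher. Both MUC5B probe sets were called absent on every array, so MUC5B has no fold here.

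The retinoid list had 11 of 19 members at least 2-fold higher and 2 at least 2-fold lower, with a median of 1.55 (random range -0.40 to 0.35). Besides the retinoid genes above, STRA6, the receptor for retinol-binding protein, read 45.9 without RA and 331.1 with it, and TGM2, tissue transglutaminase, read 21.0 and 294.6. The lower members were ADH7, an alcohol dehydrogenase, and RARB, the retinoic acid receptor beta gene, which was 2.07-fold lower on its brightest probe set while another gave a log2 ratio of 0.55. The interferon response list had 10 of 25 members at least 2-fold higher and 1 lower, with a median of 0.86 (random range -0.31 to 0.33). IRF9 (3.96-fold), the immunoproteasome subunit PSMB8 (3.84-fold) and the antiviral GTPase MX1 (3.55-fold) were among them. In the list of IL-17A and NF-kB targets 10 of 35 members were at least 2-fold higher and 5 lower, with a median of 0.51 (random range -0.31 to 0.23), and CXCL8, a neutrophil chemokine, was 4.1-fold higher. The cell cycle list had 6 of 35 members at least 2-fold lower and 1 higher, with a median of -0.40 (random range -0.27 to 0.25), and its lower members included the mitotic checkpoint gene MAD2L1 (2.86-fold) and the spindle gene PRC1 (2.5-fold). All 30 ribosomal protein genes were lower, with a median of -0.58 (random range -0.44 to 0.20) and -0.19 after quantile normalization, while only RPL18 passed 2-fold.

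For the remaining lists the median lay within the range of random lists. The stress and heat shock list (median -0.11, 28 members) had 3 members at least 2-fold higher and 6 lower, the lower ones including ASNS, asparagine synthetase (5.73-fold), and SLC7A11, a cystine transporter (at least 4.12-fold). The cholesterol synthesis list (0.29, 20 members) had 6 higher, among them FASN, fatty acid synthase (3-fold). The basal cell list (0.25, 17 members) had 5 higher, among them the matrix gene TNC (at least 8.07-fold), and 1 lower, EGFR. As given above, EGFR passed 2-fold on its brightest probe set, and its other measured probe sets differed in sign. The list of IL-6 and STAT3 targets (0.28, 20 members) had 5 higher, SERPINA3, FOS, IRF1, STAT3 and TIMP1, and 1 lower, PIM1. The cytokine receptor list (0.08, 18 members) had 1 higher, STAT3, and 2 lower, EGFR (with the same limit) and IL22RA1. No ciliated cell gene of 5 measured passed 2-fold (0.12). Of other cell types, the fibroblast list (-0.12, 6 members) had FBLN1 at least 4.37-fold higher and S100A4 3.45-fold lower, the leukocyte list (0.32, 7 members) had CD14 at least 8.5-fold higher, and the cartilage list (0.40, 3 members) had SOX9 at least 2.33-fold higher. Too few endothelial markers had a fold for a median, and the measured one, ROBO4, was 1.37-fold higher.

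The differences between these arrays outnumbered those in simulated unchanged arrays, where at most 24 genes were 2-fold higher and at most 29 lower in 100 draws. The simulated spread came from IL-17A and IL-6, the most alike arrays (r 0.979, against 0.909 for RA with no RA). Even for that pair the simulation gave at most 23 genes higher and 23 lower, against 37 and 36 on the arrays. The excess therefore does not show what set the RA and no RA arrays apart. The array without RA stood at least 2-fold from each of the other arrays for 157 genes on the high side and 219 on the low side, and the RA array for 5 and 30. The array without RA also had the highest 3' to 5' signal ratios, a sign of RNA integrity, with 2.20 for GAPDH (1.69 with RA, 1.58 with IL-6, 1.61 with IL-17A) and 2.58 for ACTB (2.25, 1.80 and 2.38). With 1 array per group, an effect of RA and a difference in RNA quality between these arrays were not separated. Where a gene had another measured probe set, 92 of 100 higher and 99 of 109 lower genes differed in the same direction on it, but only 45 of the 100 and 37 of the 109 also passed 2-fold there, with median log2 ratios of 0.86 and -0.84.

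The second comparison asked which genes differed in the culture given IL-6. The labels do not say whether the cytokine cultures also received RA, so a gene was counted only if it differed in the same direction from both arrays without cytokine. CXCL8 was 9.27-fold higher than without RA and 2.26-fold higher than with RA (1808.8 with IL-6). ANGPTL4, a secreted inhibitor of lipoprotein lipase, was at least 3.31-fold higher than either array (115.0 with IL-6), and DMBT1, a secreted scavenger receptor of mucosal defence, was 4.51-fold and 2.14-fold higher. HSD11B2, which inactivates cortisol, was 2.69-fold lower than without RA and 2.33-fold lower than with RA, and SECTM1, a transmembrane and secreted immune protein, was 2.58-fold lower than either.

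In all 17 genes were at least 2-fold higher and 6 at least 2-fold lower among 5793 with a fold from both arrays. SERPINB4 was at least 7.28-fold higher than without RA and 2.41-fold higher than with RA. LGALS1, the lectin galectin, was 2.26-fold and 2.52-fold higher, NRIP1, a nuclear receptor corepressor, was 2.13-fold and 2.5-fold higher, and MBNL1, a splicing regulator, was 2.33-fold and 4.28-fold higher. RAI14 was at least 2.62-fold and CLEC2B, a C-type lectin, at least 2.31-fold higher than either array. FNDC3B (2.64-fold and at least 6.17-fold), FMO2, a flavin monooxygenase (at least 2.16-fold and at least 2.33-fold), and EHBP1 (2.15-fold and 2.08-fold) complete the named higher genes. The remaining lower genes were RNASE1, a secreted ribonuclease (2.2-fold and 2.52-fold), CKB, creatine kinase B (9.14-fold and 2.07-fold), the histone gene H2AC25 (2.82-fold and 2.14-fold) and TCEAL1 (2.11-fold and 2.23-fold).

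No member of the list of IL-6 and STAT3 targets passed 2-fold over both arrays. The list's median log2 ratio was 0.38 over the mean of the arrays without cytokine (random range -0.19 to 0.17), 0.59 over the array without RA alone and 0.00 over the array with RA alone. SERPINA3 read 2357.8 with IL-6, which was 1.1-fold higher than with RA. SOCS3, a feedback inhibitor of IL-6 signalling, was called absent on all arrays by its brightest probe set, and a second one was present on the IL-6 array only, where it was at least 1.41-fold higher (49.1 with IL-6). IL6 itself was near the floor on every array (26.7 with IL-6). The squamous list had a median of -0.75 over the mean of the arrays without cytokine and 0.01 over the RA array alone, and the mucous list 0.14 and -0.05. MUC5AC on its second probe set read 79.2, which was 1.5-fold lower than with RA. Over the RA array alone the cell cycle list had a median of 0.26 (random range -0.15 to 0.17), with CCNB2, a mitotic cyclin, 2.37-fold higher, and the interferon list a median of -0.23 (random range -0.18 to 0.16). Both signs depended on the control array, since over the array without RA the medians were -0.03 and 0.65. The basal cell list lay above its random range with every control, with medians of 0.47 over the mean of the arrays without cytokine (range -0.23 to 0.18), 0.50 over the array without RA (-0.36 to 0.33) and 0.14 over the array with RA (-0.22 to 0.11), and no member passed 2-fold over both arrays. Over the RA array the stress and heat shock list (0.14, range -0.18 to 0.09) and the ribosomal protein list (0.08, range -0.17 to 0.05) also lay above their ranges. The sign of the ribosomal protein list depended on the control too, with -0.52 over the array without RA (range -0.44 to 0.16). The IL-6 array had the lowest 3' to 5' ratios of ACTB and GAPDH (1.80 and 1.58) and the most probe sets called present, so RNA quality and IL-6 were not separated in these list medians.

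Unchanged arrays simulated in the same way, with the same limit on their spread, gave at most 8 genes 2-fold higher and 3 lower over both arrays. The count of higher genes was 5 without probe sets of shared sequence, and with a single control array it was 380 over the array without RA and 119 over the array with RA.

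The third comparison asked the same of the culture given IL-17A. Of the genes at least 2-fold higher than on both arrays without cytokine, 10 were on the fixed list of IL-17A and NF-kB targets, and 4 of these follow. CSF3, the granulocyte colony-stimulating factor, was at least 7.81-fold higher than either (271.7 with IL-17A). CCL20, a chemokine for dendritic cells and lymphocytes, was at least 16.9-fold higher than without RA and at least 6.39-fold higher than with RA (588.5), and CXCL1, a neutrophil chemokine, was 15.5-fold and 4.02-fold higher (2901.8). IL19, a cytokine of the IL-10 family, was at least 26.9-fold and 6.37-fold higher (2187.1). FCGBP, a member of the mucous list, was at least 48.7-fold and 4.61-fold higher.

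Over both arrays 32 genes were at least 2-fold higher and 5 at least 2-fold lower, among 5701 with a fold from both. The chemokine gene CXCL2 was 9.37-fold and 2.87-fold higher and CXCL3 at least 4.81-fold and 3.01-fold higher. PDZK1IP1, a small membrane protein of epithelia, was 6.69-fold and 3.35-fold higher, ALPL, alkaline phosphatase, was 3.51-fold and 3.34-fold higher, and SERPINB4 was at least 9.38-fold and 3.1-fold higher. SPRR2C, of the small proline-rich family, was at least 3.74-fold and at least 5.17-fold higher, and its close paralogs leave the source of that signal uncertain. FNDC3B was 3.03-fold and at least 7.09-fold higher. TGM1 was 4.02-fold lower than without RA and 2.15-fold lower than with RA, TM4SF1, a tetraspanin-like membrane protein, was 3.18-fold and 2.44-fold lower, and HSD11B2 was at least 3.54-fold and at least 3.06-fold lower. FAM114A2 was at least 2.35-fold and at least 2.08-fold lower. RBM5, a splicing factor, was at least 4.94-fold and at least 4.28-fold lower on its brightest probe set, while another gave log2 ratios of -0.56 and -0.06.

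In the list of IL-17A and NF-kB targets 10 members passed 2-fold over both arrays and all 10 were higher. They were CSF3, CCL20, IL19, CXCL1, CXCL2, CXCL3, CXCL5, CXCL8, PDZK1IP1 and the antimicrobial gene S100A7. The list's median was 0.38 over the mean of the arrays without cytokine (random range -0.13 to 0.09), 0.66 over the array without RA and 0.53 over the array with RA (random range -0.13 to 0.13). Other lists outside their random ranges over the RA array were ribosomal protein (0.23, range -0.09 to 0.16, 29 of 30 members higher), stress and heat shock (0.20, range -0.15 to 0.13) and cholesterol synthesis (-0.19, range -0.18 to 0.15). The signs of ribosomal protein and cholesterol synthesis depended on the control array. Over the array without RA they were -0.38 (range -0.32 to 0.17) and 0.46 (range -0.27 to 0.33). Spike-in control probe sets had median log2 ratios of -0.31 for RA, -0.44 for IL-6 and -0.14 for IL-17A, each over no RA. A scaling difference was therefore not separated from the sign of the ribosomal protein medians, but it would move the random ranges with them. The squamous list had a median of -0.78 over the mean of the arrays without cytokine and 0.02 over the RA array, with LY6D, SERPINB4 and SPRR2C higher and TGM1 lower over both arrays. The mucous list had a median of 0.36 over the mean and -0.09 over the RA array, and FCGBP was its member past 2-fold over both. MUC5AC on its second probe set was 1.13-fold lower than with RA (105.0 with IL-17A). In the list of IL-6 and STAT3 targets no member passed 2-fold over both arrays, and CEBPD, a transcription factor of the acute phase, was 2.3-fold and 1.98-fold higher. IL6 was at least 1.14-fold higher than on each other array (39.8 with IL-17A).

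**Figure D2:**
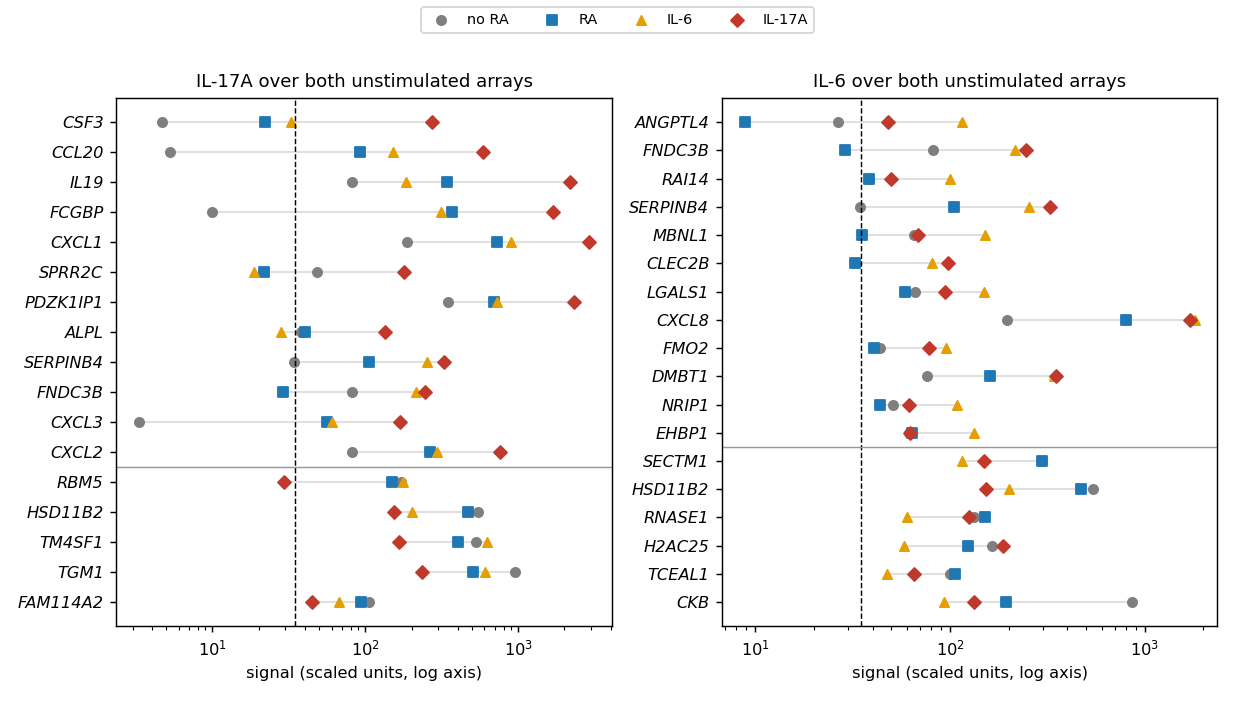
Signal on each of the 4 arrays (log axis, scaled units) for the named genes past 2-fold over both arrays without cytokine, for IL-17A (left) and IL-6 (right), with higher genes above the grey line, lower genes below it and the floor of 34.8 as a dashed line. CCL20 reads 588.5 with IL-17A against 5.3, 92.1 and 150.5 on the arrays without RA, with RA and with IL-6.

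Simulated unchanged arrays, with the same limit on their spread, gave at most 9 genes 2-fold higher and at most 5 lower. The 5 lower genes are thus no more than that simulation reached. The count of higher genes was 18 without probe sets of shared sequence, and with a single control array it was 321 over the array without RA and 87 over the array with RA.

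IL-17A was then set against IL-6, given at the same mass dose for the same time. SPRR2B was 12.3-fold higher with IL-17A (249.5 and 3069.1), on a probe set that shares sequence with its paralogs, and IL19 was 11.9-fold higher. CSF3 was at least 7.81-fold, FCGBP 5.43-fold, CCL20 3.91-fold and CXCL1 3.24-fold higher. DUOX2, an epithelial oxidase that makes hydrogen peroxide, was 5.38-fold higher, and S100A7 was at least 3.96-fold higher. TM4SF1 was 3.79-fold lower and TGM1 2.59-fold lower with IL-17A than with IL-6, and ANGPTL4 was at least 2.39-fold lower.

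Among 5976 genes with a fold, 37 were at least 2-fold higher with IL-17A and 36 at least 2-fold lower. SPRR2C (at least 5.17-fold), the tetraspanin CD82 (4.7-fold), ALPL (at least 3.84-fold) and H2AC25 (3.23-fold) were among the higher genes. The lower genes included SERPINB13, a keratinocyte protease inhibitor (2.44-fold), DST, a linker of hemidesmosomes to keratin (2.53-fold), the coactivator gene WWTR1 (2.42-fold), the selenium transporter gene SELENOP (2.34-fold) and IGF2BP2, an RNA-binding protein (at least 2.36-fold). BCL9, a cofactor of Wnt signalling, was at least 2.57-fold lower, YTHDF3, a reader of methylated RNA, 2.55-fold, APPBP2 2.46-fold and NAV2 2.45-fold. Of the IL-17A and NF-kB targets 9 of 39 were at least 2-fold higher and none lower, with a median of 0.40 (random range -0.11 to 0.11). The basal cell list had a median of -0.33 (random range -0.13 to 0.18), with SNAI2 1.72-fold lower and DST past 2-fold lower, but over the array with RA it was 0.14 for IL-6 and -0.06 for IL-17A, the latter within its random range of -0.20 to 0.18. The 3' to 5' ratio differed between these arrays for ACTB (2.38 with IL-17A and 1.80 with IL-6) and little for GAPDH (1.61 and 1.58), so a difference in RNA quality was not separated from this shift. The list of IL-6 and STAT3 targets had a median of -0.18 (random range -0.15 to 0.15), with no member past 2-fold. Over the array with RA its median was 0.00 for IL-6 (range -0.19 to 0.13) and -0.05 for IL-17A (range -0.19 to 0.16), each within its range. The simulated arrays give no reference here, because their spread was taken from these same arrays. Of 8 higher genes with another measured probe set, 5 differed in the same direction on it, and of 9 lower genes, 9 did, while 0 of the 8 and 1 of the 9 also passed 2-fold there. The median log2 ratios on those other probe sets were 0.05 and -0.53, so for these 8 genes they showed almost no increase.

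**Figure D3:**
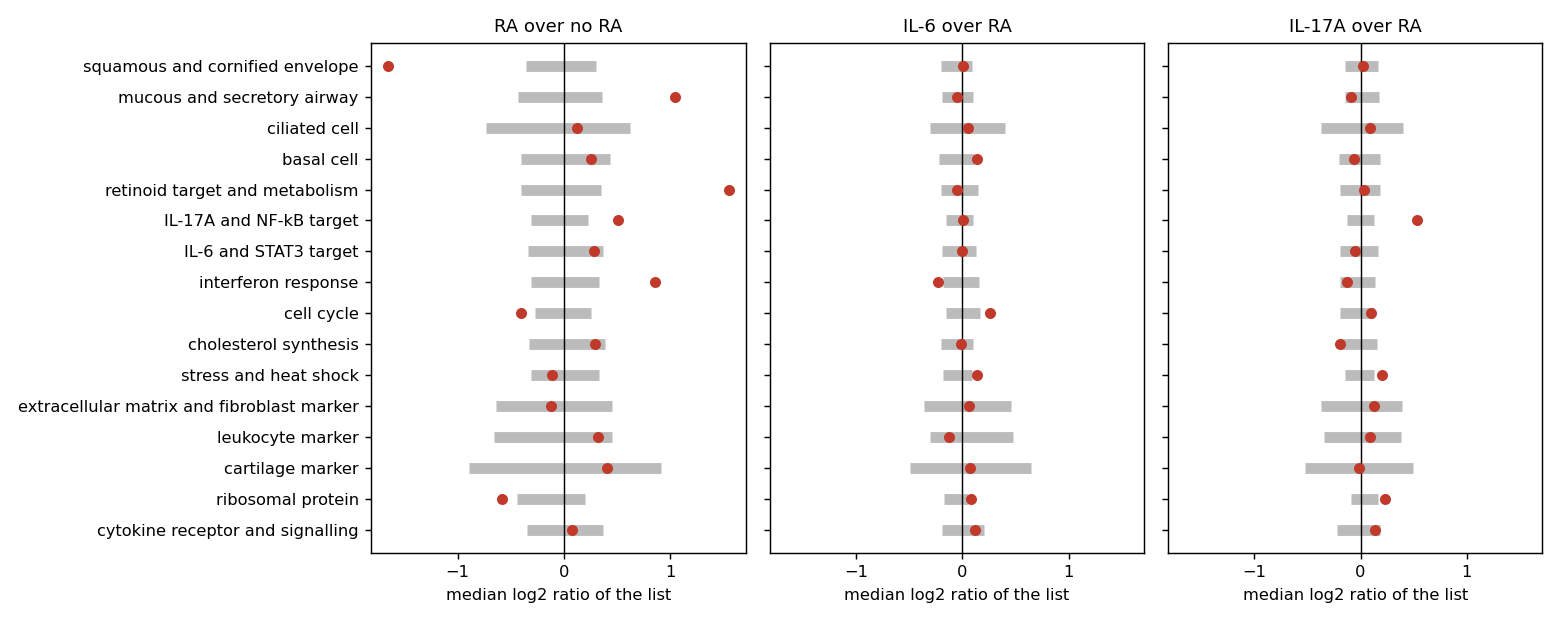
Median log2 ratio (horizontal axis) of each gene list for RA over no RA, IL-6 over RA and IL-17A over RA, 1 array per group, as red points, with grey bars for the central 95 percent of 10000 random lists matched on expression. The squamous list lies at -1.65 and the retinoid list at 1.55 for RA, and the IL-17A and NF-kB list lies at 0.53 for IL-17A.

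The last comparison asked how far the IL-6 and IL-17A differences overlapped. CXCL8, DMBT1, SERPINB4, CLEC2B, FNDC3B, APOL1 and APOL2 were at least 2-fold higher over both arrays with each cytokine, and HSD11B2 was lower with each. These were 7 shared genes of 17 and 32 higher among 5481 tested in both, where independent lists would share 0.10 and simulated unchanged arrays shared at most 1. Both cytokines were set against the same control arrays, which cannot be split, so part of the excess may come from the shared controls. Across 6143 genes, which are not independent replicates, the log2 ratios of the cytokines over the mean of the control arrays had a Pearson r of 0.64 and a covariance of 0.111. Simulated unchanged arrays gave an r of 0.34 and a covariance of 0.027, a difference in covariance of 0.085. That difference is no estimate of a shared cytokine effect, because the simulation holds no difference between the control arrays. On the arrays each control deviated from their mean with a variance of 0.152 across the same genes, and cytokine cultures closer to one control than to the other would share part of that deviation. Both cytokine arrays did lie closer to the RA array for most genes that differed with RA. These were 89.3% (IL-6) and 84.3% (IL-17A) of the higher genes and 72.8% and 70.7% of the lower ones. With a different control array for each cytokine r was -0.15 (IL-6 over no RA and IL-17A over RA) and -0.16 (the reverse). There the difference between the control arrays enters the cytokine ratios with opposite signs, which lowers r by construction. The negative sign therefore says nothing about what the cytokines share.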

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

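The counts of genes past the threshold stayed within 1.5 times the main count in 46 of 96 settings and moved further in 50. Of 499 list medians, 399 moved by less than the SD of random lists. Single-gene ratios were rerun only for the up to 12 most changed genes per direction, where a ratio could be computed. Of these 615 ratios, 523 moved by less than the simulated SD of an array, and none changed sign. Genes named only as list members or as fixed genes were not rerun. No paired analysis was possible because each group has 1 array. The other deposited table was not run as an alternative, since its values were identical. Counts follow in the order higher and lower, with the main counts 477 and 416 for RA, 17 and 6 for IL-6, 32 and 5 for IL-17A, and 37 and 36 for IL-17A over IL-6. By construction a 1.5-fold threshold gave more genes (1131 and 1123 for RA, 124 and 51 for IL-6, 91 and 76 for IL-17A, 216 and 340 for IL-17A over IL-6) and a 3-fold threshold fewer (135 and 140, 1 and 0, 11 and 2, 14 and 1). A single control array, which drops a condition by construction, gave 380 and 292 for IL-6 and 321 and 271 for IL-17A over no RA, and 119 and 27 and 87 and 44 over RA. Without probe sets of shared sequence fewer genes were tested, with 287 and 241 for RA, 5 higher for IL-6, 18 higher for IL-17A and 17 lower for IL-17A over IL-6. A floor at 0.25 times its value gave 31 and 11 for IL-6, 17 lower for IL-17A, and 65 and 99 for IL-17A over IL-6, and a doubled floor gave 8 and 3 for IL-6 and 16 lower for IL-17A over IL-6. The present call in place of the floor gave 30 higher for IL-6, 17 lower for IL-17A, and 59 and 98 for IL-17A over IL-6. The mean of probe sets gave 8 lower for IL-17A. Requiring another measured probe set in the same direction, chosen after seeing the data, left 92 and 99 for RA, 3 and 0 for IL-6, 4 and 2 for IL-17A, and 5 and 9 for IL-17A over IL-6, because few genes have such a probe set. Signs are given here only for list medians outside the range of random lists in the main setting, and some medians within that range also changed sign, such as mucous for IL-6 (0.14 over the mean of the control arrays, -0.05 over RA). Ribosomal protein did so for IL-6 (-0.24 and 0.08) and IL-17A (-0.08 and 0.23), and cholesterol synthesis for IL-17A (0.05 and -0.19). Medians outside that range that changed sign over the RA array alone were, for IL-6, squamous (0.01), retinoid (-0.05) and interferon (-0.23), and for IL-17A squamous (0.02), mucous (-0.09), basal cell (-0.06), IL-6 and STAT3 (-0.05) and interferon (-0.13). The cell cycle list for IL-6 changed sign over no RA alone (-0.03), and the basal cell list for IL-17A without shared-sequence probe sets (-0.11). The correlation of the cytokine ratios was 0.61 with the present call and negative with a different control for each cytokine (-0.15 and -0.16). The difference between the control arrays pushes that value down by construction, so its sign is no evidence of opposite responses. Beyond what the settings' construction shows, the cause was not tested. Signal over background limits the dim genes, and with a doubled floor 64 of 83 ratios of the most changed genes stayed past 2-fold.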

Other observations

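The tests on ribosomal protein genes and on SPRR2 genes below were chosen after their results were seen. On the cytokine arrays, the genes that differed between the arrays with and without RA mostly read closer to the array with RA. Of the 477 genes at least 2-fold higher with RA, 426 (89.3%) lay nearer to the RA array on the IL-6 array and 402 (84.3%) on the IL-17A array. Of the 416 lower genes, 303 (72.8%) and 294 (70.7%) did. Median log2 ratios of the higher genes were 1.30 for RA over no RA, and over the RA array -0.28 with IL-6 and -0.31 with IL-17A. CYP26A1 read 79.1 without RA, 1760.8 with RA, 929.7 with IL-6 and 847.8 with IL-17A. The retinoid list had medians of 1.30 with IL-6 and 1.37 with IL-17A over the array without RA. Over the RA array they were -0.05 and 0.03. On these genes both cytokine arrays resembled the RA array. Medians over the mean of the control arrays can therefore hold part of the difference between those controls. The labels do not say what medium the cytokine cultures had.

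All 30 ribosomal protein genes measured were dimmer with RA than without, with a median log2 ratio of -0.58 and a bootstrap SE of 0.05. A single scaling factor for the whole array moves all genes alike, so it cannot by itself set the list apart from other genes. It stays open for the absolute level of the list. The 9 spike-in probe sets had a median of -0.31 (SD 0.21), which is farther from the list's median than that SD, but their range of -0.65 to 0.11 includes it. The median over all genes present on the arrays (-0.01) decides nothing about the absolute level, since the deposited scaling sets it. It shows only that the list lay below other genes. A difference that grows with brightness also stays open. The list's median stood at percentile 2.2 of random lists of genes as bright (median -0.40, range -0.57 to -0.11), which is outside that range by less than its SE, and quantile normalization brought it to -0.19. With 1 array per group, a change of these transcripts relative to other genes cannot be told apart from a brightness-dependent difference. An absolute change cannot be told apart from a scaling factor either.

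The RA array stood at least 2-fold from each other array for 5 genes on the high side and 30 on the low side, among them EGFR, UGCG (553.5 without RA, 61.8 with RA, 329.7 with IL-6 and 371.4 with IL-17A) and KIF5B. If faulty or off-target probe sets were the source, other probe sets of these genes would not follow. Of 15 genes with another measured probe set 80.0% went the same way on it (95% exact interval 51.9 to 95.7), with a median size of 0.34 on the log2 scale against 1.49, and 1 passed 2-fold. For the array without RA the share was 93.2% of 73 genes, with sizes of 1.13 and 1.68. The 15 genes are too few to decide, and an effect of RA that is absent with the cytokines was not tested.

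SPRR2B read 2941.9 without RA, 370.4 with RA, 249.5 with IL-6 and 3069.1 with IL-17A, and SPRR2C was higher with IL-17A than on each other array. A general return of cornified envelope genes toward the level without RA is argued against. The median log2 ratio of IL-17A over RA was 0.02 (bootstrap SE 0.10) over 12 other list members that were lower with RA, against 3.05 for SPRR2B and 2.37 for SPRR2C. These 12 were the members with a fold among 15 lower with RA, and 8 were higher and 4 lower with IL-17A. Beyond SPRR2 genes, KLK10 and LY6D of this list were at least 2-fold higher with IL-17A than with IL-6, and SERPINB13 and TGM1 at least 2-fold lower. Signal shared among SPRR2 paralogs stays open, because the SPRR2B probe set is one of shared sequence, so which SPRR2 gene gave the signal is not known. An increase of SPRR2 transcripts with IL-17A may be a specific response, as a hypothesis found on these same arrays. That hypothesis was not tested, since only a general return of other envelope genes was.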
